A study of Mus musculus with 6 samples.

How the data were processed

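Messenger RNA was measured by sequencing in 6 wells of mouse macrophages grown from bone marrow with macrophage colony-stimulating factor (M-CSF). Per the labels' protocols, 3 wells stayed in RPMI-1640 medium with serum and M-CSF, and 3 wells received that medium mixed in equal volumes with medium conditioned by LL-2 cells, a Lewis lung carcinoma line. All wells were lysed after 24 h. RNA was enriched with oligo(dT) beads and reverse transcribed from random hexamers. The labels' protocols do not say whether the libraries keep strand. Each sample was placed in its group by its treatment label.

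The deposited table holds whole-number counts per gene, 1 column per library, with gene coordinates. Per the submitters' processing notes, reads were aligned to GRCm38 with HISAT2 and counted with featureCounts. Versions, the strand setting, the annotation release and the handling of reads that map to several places are not given in the sources used here. Counts of genes that overlap on opposite strands and of near-identical gene copies are uncertain for that reason. The table lists 55421 genes by Ensembl identifier. Of these, 55240 were matched by identifier to GENCODE release M21, which supplied symbols and gene types, and 54985 had the same start and end there. The unmatched genes held 0.0017% of counts, and 0 rows named no gene. Coordinates are those of the deposited table.

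Total counts were 24179548, 24547091 and 25916709 in the untreated libraries and 29801669, 30040682 and 28447825 in the conditioned-medium libraries. At this depth, a gene with 0 counts in a library has an upper limit of 3 counts, or 0.1 to 0.124 CPM (counts scaled to the library total), which covers counting error only. Libraries of one group differed by more than sampling noise, so none was treated as a copy of another.

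Genes were kept by filterByExpr on the groups, libraries were scaled by TMM, and the groups were compared with edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3). The design held the group alone. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05, and every adjusted p of a gene given here comes from this test unless another is named. The edgeR function glmTreat tested for changes beyond 1.5-fold. Log2 fold changes are conditioned medium minus untreated, and their standard errors (SE) were derived from the F statistic. Levels are TMM-scaled CPM.

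Before the data were examined, 45 gene lists were fixed. The 44 with at least 5 tested genes were tested with camera at a preset inter-gene correlation of 0.01 and adjusted over the lists. Camera with an estimated correlation and fry were run beside it. Named genes followed a rule fixed at the same time. It took the 12 largest rises and the 12 largest falls among genes past the threshold with a non-model symbol, a mean of at least 5 CPM and groups that did not overlap. It added, for each list, the 3 members with the largest change past the threshold, or the member with the smallest p where none passed. Arg1, Mrc1, Nos2, Il1b, Il10, Vegfa, Cd274, Csf1r, Adgre1 and Ccl2 were always included. Genes of lists that are only summarised may be left out, and a few genes the rule names are not reported here. The rule also asked for protein-coding genes where the table gives a gene type, which it does not.

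The replicate numbers in the labels are shared by the groups, and no label says what they stand for. Whether they pair the wells was checked by correlating deviations from the group means over 13853 genes. The correlation was 0.328, 0.161 and 0.309 for wells of the same number and -0.289 to 0.011 for wells of different numbers. Deviations from a group mean cancel out within the group, so positive values for the same number force lower values elsewhere on average. So few wells allow few matchings, and this matching could rank best by chance. The check therefore does not settle whether the numbers pair the wells. Wells of the same number are called pairs below. Counts, p-values and SE come from the fit without the replicate number unless stated. A fit with that number as a block called 5023 changed genes, against 3861 without it, and is given where it changes a call. Nothing in the labels says that the wells came from separate animals, so p-values measure the spread between these wells, which may be technical.

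The alternatives were RLE scaling, no scaling beyond the total count, DESeq2 1.42.0, limma-voom, robust dispersion, no low-count filter, a mean of at least 1 CPM, protein-coding genes only, the replicate block, and leaving out each library in turn. After the data were seen, leaving out both libraries of pair 3 and thinning every library to the smallest total were added. The scripts were tested on simulated data with the means, library sizes and trended dispersions of this comparison and 200 changed genes among 13853. Genes were drawn independently, with no replicate effect and fewer changed genes than were called here. The shares that follow check the scripts and do not measure the power or error rate of this comparison. The share recovered was 28.0% at 1.25-fold, 71.4% at 1.5-fold, 83.7% at 2-fold and 100% at 4-fold, and 2.1% of calls were unchanged genes.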

Results

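The series measured gene expression in mouse bone marrow-derived macrophages after 24 h in medium conditioned by LL-2 lung carcinoma cells. It held 3 untreated wells and 3 wells in 50% conditioned medium. The libraries held 24179548 to 30040682 counts, and each conditioned-medium library was deeper than each untreated library. Lyz2, the macrophage lysozyme gene, was the most abundant transcript in each library, at 4.14% to 5.27% of counts, and mitochondrial transcripts took 1.15% to 1.27%. The comparison asks which macrophage genes change in conditioned medium. No wells in medium conditioned by other cells were analysed here, so it does not separate tumour-cell products from conditioning as such. Mixing in equal volumes also reduced the share of fresh medium and may have diluted its M-CSF, which the comparison cannot separate either.

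Of 13853 tested genes, 3861 changed (27.9%), 1749 of them higher and 2112 lower with conditioned medium. By more than 2-fold, 238 genes were higher and 415 lower. Changes beyond 1.5-fold were called for 483 genes by glmTreat, 172 higher and 311 lower, and for 735 with the replicate number as a block. Without scaling beyond the total count, 2656 genes were higher and 1710 lower, so that 60.8% of calls were higher, against 45.3% with TMM scaling. The count of higher genes fell to 1146 without untreated replicate 2 and to 1160 without conditioned-medium replicate 1, where glmTreat called 317 and 298. The groups did not overlap for 5929 tested genes (42.8%, against 10% by chance if all wells were alike and unpaired). The leading principal component held 54.2% of the variance and separated the groups, and the next held 17.9% and set the wells numbered 3 apart from the others.

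**Figure D1:**
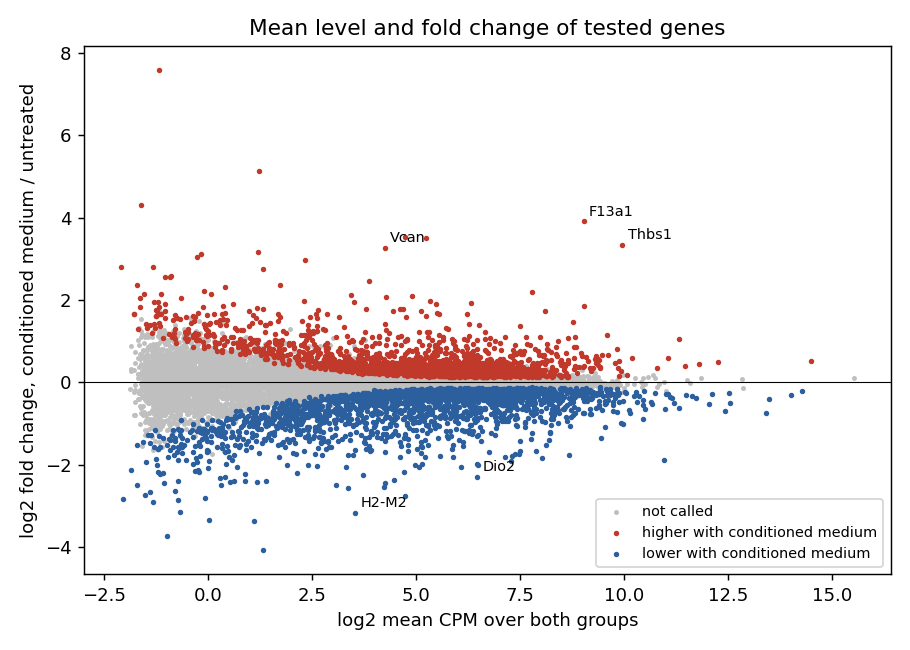
Log2 fold change (conditioned medium over untreated) against log2 mean CPM for the 13853 tested genes, 1 point per gene, coloured by edgeR call. The 1749 higher and 2112 lower genes are spread over the range of expression, and F13a1 and Thbs1 stand out among abundant genes.

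The largest rise under the naming rule was that of F13a1, which encodes the A subunit of coagulation factor XIII (ENSMUSG00000039109, chromosome 13, 36867178 to 37050244, GRCm38). It rose 15.1-fold, from 65.0 ± 5.86 to 981 ± 4.65 CPM (SD, n = 3 per group), with a log2 fold change of 3.92 (SE 0.07, adjusted p = 6.05e-09). Thbs1, encoding the matrix glycoprotein thrombospondin (chromosome 2, 118111876 to 118127133), rose 10.1-fold, from 179 ± 11.9 to 1816 ± 187 CPM (adjusted p = 1.04e-07). Cd163, the haemoglobin-haptoglobin scavenger receptor, rose 11.3-fold from 6.16 ± 2.07 to 70.0 ± 4.48 CPM. Cd38, an ectoenzyme that consumes NAD, rose 11.6-fold to 48.8 ± 13.5 CPM, and Vcan, the proteoglycan versican, rose 9.62-fold to 34.3 ± 14.2 CPM. The lectin receptor gene Clec4n rose 4.61-fold to 366 ± 22.1 CPM. Fkbp5, an immunophilin that binds the glucocorticoid receptor complex, rose 4.25-fold from 11.4 ± 0.764 to 48.5 ± 1.21 CPM. Jaml, Dnah2, Acpp, Mtus1 and Il1b rose by log2 fold changes of 2.47, 2.13, 2.06, 1.98 and 1.94.

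H2-M2, a nonclassical MHC class I gene, fell the most under the rule (chromosome 17, 37480851 to 37483552). It was 8.95-fold lower, going from 20.9 ± 3.66 to 2.33 ± 0.344 CPM (log2 fold change -3.16, SE 0.16, adjusted p = 1.99e-06). Slc13a3, a dicarboxylate transporter gene, was 6.78-fold lower, and Fabp3, a fatty acid binding protein gene, was 5.88-fold lower. Ccnd1, encoding cyclin D1, was 5.15-fold lower. Fabp3 and Ccnd1 each overlap an expressed gene on the opposite strand, so their counts are uncertain. Dio2, a thyroid hormone deiodinase gene, went from 147 ± 18.8 to 30.02 ± 4.96 CPM. Lox, a collagen cross-linking enzyme gene, went from 108 ± 8.89 to 26.2 ± 3.50 CPM. Mamdc2, Slamf9, Pcp4l1, Ifit3b and Cd200 had log2 fold changes of -2.55, -2.24, -2.16, -2.06 and -2.04.

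**Figure D2:**
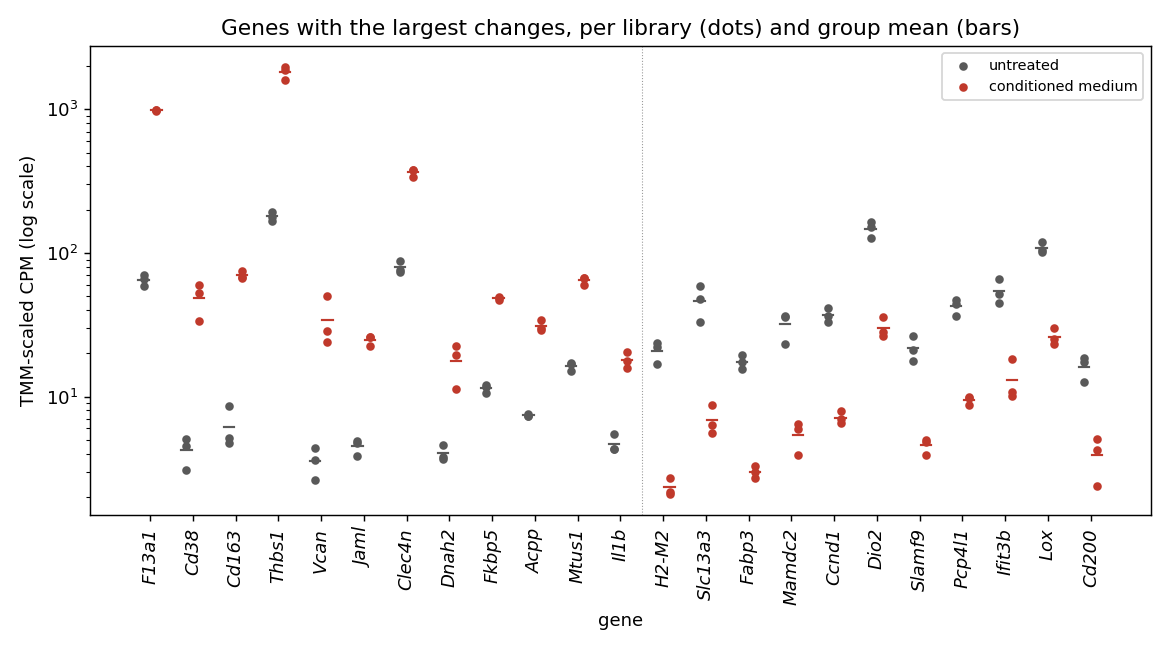
TMM-scaled CPM (log axis) of the largest rises and falls named in the text, with 1 dot per library and a bar at each group mean. For each gene the 3 untreated wells lie apart from the 3 conditioned-medium wells, because the naming rule required groups that did not overlap.

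Camera with the preset correlation called 14 of 44 gene lists, 5 higher and 9 lower. With an estimated correlation it called 0, and fry called 18. The camera calls therefore rest on the preset correlation. Among the 14 called lists the estimated correlation ran from 0.008 for monocyte markers to 0.941 for the interferon response. Where it lies above the preset 0.01, the preset p-values are too small if the estimate holds. Fry sets no correlation and does not compare a list with other genes, and it called each of the 14 lists except interferon gamma. The counts of members below come from the gene-level test. Some lists share members, such as Ldha in hypoxia and glycolysis and Lipa in lipid-associated macrophages and lysosomes. Tap1 stands in both the interferon gamma and the MHC class I list. Calls of lists that share members are not separate evidence.

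Interferon-induced genes fell together. All 29 tested type I interferon response genes fell (29 adjusted over the list alone), with a median log2 fold change of -1.24. Ifit2 went from 407 ± 94.98 to 115 ± 42.1 CPM and Ifit3 from 245 ± 45.3 to 65.7 ± 23.6 CPM. Ifit3 and Ifit3b are close paralogs whose reads may be split between them. The list's camera adjusted p was 2.74e-17, and adjusted p = 0.601 with an estimated correlation. Of 20 interferon gamma response genes, 15 fell and 1 rose (16 and 1 adjusted over the list alone; camera adjusted p = 0.000243, and adjusted p = 0.747 with an estimated correlation). That call was lost by fry (adjusted p = 0.102) but kept by fry with the replicate block (adjusted p = 0.0487). Among them Cxcl10, a chemokine gene, was 3.46-fold lower. Of 19 MHC class I genes, 17 fell (19 adjusted over the list alone), including H2-T23, from 548 ± 35.7 to 304 ± 25.3 CPM (camera adjusted p = 1.73e-10, and adjusted p = 0.601 with an estimated correlation). H2-Q6 and H2-Q7, which fell by log2 fold changes of -1.32 and -1.08, are near-identical copies and their counts are uncertain.

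Of 11 MHC class II genes, 5 fell (5 adjusted over the list alone), among them Ctss (log2 fold change -0.69), H2-Eb1 (-0.45) and H2-Aa (-0.44). The camera adjusted p was 0.0350, and adjusted p = 0.697 with an estimated correlation. That call was lost with the replicate block (adjusted p = 0.0758), without conditioned-medium replicate 3 (0.0558) and without untreated replicate 3 (0.0934). In the same wells 6 of 11 dendritic cell markers fell and 1 rose (7 and 1 adjusted over the list alone; camera adjusted p = 0.437), with Ccl22 2.20-fold lower and Kmo 3.42-fold higher. Kmo overlaps Fh1, so both counts are uncertain.

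Activation markers moved in both directions. Of 18 alternative activation genes, 8 rose and 6 fell (9 and 7 adjusted over the list alone; camera adjusted p = 0.000687, and adjusted p = 0.402 with an estimated correlation). That call was lost with limma-voom (adjusted p = 0.147). The median of the list, 0.27, was 0.091 without conditioned-medium replicate 1 and 0.65 without untreated replicate 1. Cd163 and the chemokine gene Ccl24 rose, Ccl24 by 3.12 on the log2 scale from 0.179 ± 0.051 CPM, and the mannose receptor gene Mrc1 rose from 502 ± 26.4 to 777 ± 46.2 CPM. Egr2 fell with a log2 fold change of -2.21. Arg1, the arginase gene, was too low to test, with 13 counts in the untreated and 41 in the conditioned-medium libraries. Of 18 classical activation genes, 8 rose and 6 fell (8 and 7 adjusted over the list alone; camera adjusted p = 0.495). Il1b, encoding interleukin-1 beta, rose from 4.68 ± 0.665 to 18.0 ± 2.40 CPM, and Tnf, encoding tumour necrosis factor, fell from 29.2 ± 3.35 to 9.12 ± 1.85 CPM. Nos2, encoding inducible nitric oxide synthase, had a log2 fold change of -1.13 (SE 0.43, adjusted p = 0.0795, and 0.0356 with the replicate block).

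Cytokine genes were likewise divided. Of 21 chemokine genes, 7 rose and 7 fell (7 and 7 adjusted over the list alone; camera adjusted p = 0.994). Ccl2, a monocyte attractant gene, rose 2.38-fold to 8.58 ± 0.968 CPM and Ccl5 was 3.48-fold lower. Of 23 chemokine and cytokine receptor genes, 12 rose and 5 fell (12 and 5 adjusted over the list alone), led by the decoy receptor gene Il1r2 (log2 fold change 2.76) and Ccr1 (1.62). Their camera adjusted p was 0.0647, and 0.0172 with the replicate block and 0.0261 without conditioned-medium replicate 3. With the block and an estimated correlation it was 0.787. Il10, an anti-inflammatory cytokine gene, was 1.69-fold lower. Of 20 immune checkpoint genes, 3 rose and 5 fell (3 and 5 adjusted over the list alone, and 5 and 6 with the replicate block; camera adjusted p = 0.437), with Cd274, encoding PD-L1, 1.83-fold lower. Of 22 NF-kB feedback genes, 4 rose and 10 fell (5 and 10 adjusted over the list alone; camera adjusted p = 0.483). Socs3 and Ier3 rose by log2 fold changes of 1.73 and 1.67, and Tnip3 fell. Of 23 immediate early genes, 5 rose and 6 fell (5 and 7 adjusted over the list alone; camera adjusted p = 0.586).

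Hypoxia-induced and glycolytic genes rose. Of 25 hypoxia genes, 20 rose and 1 fell (20 and 2 adjusted over the list alone, and 20 and 2 with the replicate block; camera adjusted p = 7.96e-12, and adjusted p = 0.108 with an estimated correlation). Vegfa, the vascular endothelial growth factor gene, rose from 80.2 ± 3.98 to 160 ± 10.6 CPM. Ddit4, Egln3 and Adm, 3 genes induced by hypoxia-inducible factors, rose by log2 fold changes of 1.67, 1.66 and 2.56. Adm was scarce, going from 0.152 ± 0.105 to 0.908 ± 0.321 CPM, and its log2 fold change had an SE of 0.52. Of 22 glycolysis genes, 12 rose and 3 fell (13 and 3 adjusted over the list alone; camera adjusted p = 4.37e-05, and adjusted p = 0.673 with an estimated correlation). Slc16a3, a lactate exporter gene whose span overlaps Csnk1d, rose 2.67-fold, Pfkl rose 2.08-fold and Eno2 was 2.45-fold lower. Of 35 oxidative phosphorylation genes, 1 rose and 3 fell (0 and 2 adjusted over the list alone, and 2 and 7 with the replicate block; camera adjusted p = 0.516). Of 20 citric acid cycle genes, 4 rose and 3 fell (4 and 3 adjusted over the list alone, and 4 and 5 with the replicate block; camera adjusted p = 0.534).

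Genes of lipid-associated macrophages and lysosomes fell. Of 18 lipid-associated macrophage genes, 14 fell and 2 rose (14 and 2 adjusted over the list alone; camera adjusted p = 7.96e-12, and adjusted p = 0.601 with an estimated correlation). Lpl, encoding lipoprotein lipase, went from 3119 ± 330 to 852 ± 216 CPM, and Itgax, encoding CD11c, from 145 ± 43.9 to 36.3 ± 13.01 CPM. Of 32 lysosome genes, 23 fell and 2 rose (23 and 2 adjusted over the list alone; camera adjusted p = 5.48e-09, and adjusted p = 0.601 with an estimated correlation). Lipa, the lysosomal acid lipase gene, was 1.84-fold lower and Ctsk, encoding cathepsin K, 1.93-fold lower. Of 15 LXR targets, 6 rose and 3 fell (6 and 4 adjusted over the list alone, and 6 and 6 with the replicate block; camera adjusted p = 0.994), with the cholesterol exporter gene Abcg1 1.94-fold lower. Of 23 cholesterol synthesis genes, 4 rose and 0 fell (2 and 0 adjusted over the list alone, and 11 and 1 with the replicate block). Their camera adjusted p was 0.110, and 0.0369 with the replicate block, 0.02502 without conditioned-medium replicate 1, 0.0356 without conditioned-medium replicate 2 and 0.0164 without untreated replicate 3. With the block and an estimated correlation it was 0.787. Of 15 fatty acid synthesis genes, 3 rose and 2 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.944), and of 20 fatty acid oxidation genes, 5 rose and 1 fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.437).

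Proliferation genes fell. Of 30 S-phase genes, 24 fell and 0 rose (27 and 0 adjusted over the list alone; camera adjusted p = 6.15e-10, and adjusted p = 0.601 with an estimated correlation). Mcm5, a subunit of the replicative helicase, went from 35.6 ± 6.55 to 13.1 ± 2.08 CPM. Of 30 G2 and M phase genes, 21 fell and 0 rose (24 and 0 adjusted over the list alone, and 25 and 1 with the replicate block; camera adjusted p = 2.69e-06, and adjusted p = 0.697 with an estimated correlation), including Cenpf (log2 fold change -1.09), Cenpe (-0.88) and Plk1 (-0.83).

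Monocyte markers rose. Of 10 tested, 7 rose and 1 fell (7 and 1 adjusted over the list alone; camera adjusted p = 7.96e-12, and adjusted p = 0.0840 with an estimated correlation), led by F13a1, Vcan and Chil3, which rose 2.11-fold. In the same wells 4 of 14 neutrophil markers rose and 2 fell (10 and 3 with the replicate block), and 6 of 8 mast cell and basophil markers fell and 2 rose. Of 20 macrophage identity genes, 7 rose and 7 fell (7 and 7 adjusted over the list alone; camera adjusted p = 0.944). The M-CSF receptor gene Csf1r rose from 4085 ± 480 to 5720 ± 270 CPM, and Adgre1, encoding F4/80, fell from 2603 ± 121 to 1989 ± 52.0 CPM. Of 9 osteoclast markers, 6 fell and 0 rose (7 and 2 adjusted over the list alone, and 7 and 1 with the replicate block; camera adjusted p = 0.000574, and adjusted p = 0.601 with an estimated correlation), among them Dcstamp (log2 fold change -2.39) and Src (-1.26). Of 16 complement genes, 7 rose and 2 fell (7 and 2 adjusted over the list alone; camera adjusted p = 0.0231, and adjusted p = 0.601 with an estimated correlation). The complement call was lost without untreated replicate 1 (adjusted p = 0.0723) and with limma-voom (0.0676). Cfb, encoding the alternative pathway factor B, was 2.78-fold lower.

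**Figure D3:**
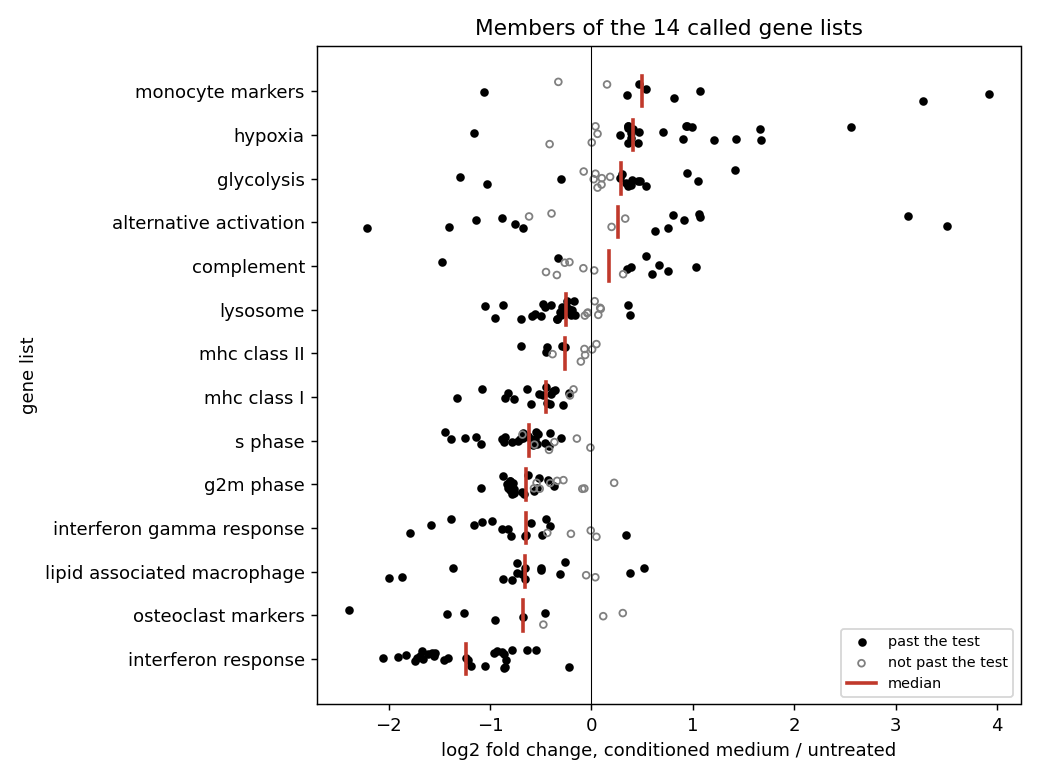
Log2 fold change of each tested member of the 14 called lists, 1 dot per gene, filled where the gene passed the edgeR test, with the list median as a red bar. Medians run from -1.24 for the interferon response list to 0.50 for the monocyte markers.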

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

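Leaving out both libraries of pair 3 and thinning to equal depth were chosen after seeing the data. The 3861 changed genes lay between 3445 (DESeq2) and 5023 (replicate block) with all libraries and full depth, and none of the genes shared with an alternative turned direction. The block kept 3857 of the 3861 and DESeq2 kept 3336. Leaving out 1 library gave 2725 to 3654 changed genes, 1146 to 1653 higher, 1579 to 2001 lower, 535 to 683 beyond 2-fold, 298 to 525 by glmTreat and 14 to 16 lists. Fewer libraries carry less power, but without both libraries of pair 3 glmTreat called 627 genes, against 483 with all libraries. Power alone thus does not account for the counts, and other causes were not tested. Without scaling beyond the total count 2656 genes were higher, since the median of all genes then moved from 0.013 to 0.070. With the replicate block glmTreat called 735 genes, and camera with an estimated correlation called 0 lists. Without pair 3 there were 4080 changed genes and with equal depth 3821. Blocked values stand in the text beside the gene and camera calls the replicate block changed and the counts of list members it moved by more than 1.5 times. Interferon gamma was lost by fry (adjusted p 0.102, and 0.0487 with the replicate block). Alternative activation was lost with limma-voom (0.147) and MHC class II without pair 3 (0.103). Without the filter camera gained cholesterol synthesis (0.0114), receptors (0.00893), neutrophil markers (0.00690), mast cell and basophil markers (0.01397) and integrated stress (0.02998). Cholesterol synthesis was also gained with limma-voom (0.0429) and receptors without scaling (0.0365). Without pair 3 receptors (0.00352), neutrophil markers (0.00190) and phagocytosis receptors (0.00129) were gained. Fry gained receptors (0.0187), integrated stress (0.0193), immune checkpoint (0.00300), the unfolded protein response (0.0187) and iron handling (0.0262). With the replicate block fry did not pass receptors (0.0737), the unfolded protein response (0.0705) or iron handling (0.243). Blocked fry also lost alternative activation (0.0592), MHC class II (0.166) and complement (0.0559) and gained mast cell and basophil markers (0.0476). The causes of these changes were not tested. DESeq2 has no camera step, so it gave no list result, and a pseudocount was not run because the table holds counts.

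Of 140 named genes over all alternatives, 83 values no longer passed the threshold, 2 newly passed it and 3 turned direction. All 3 were Epor, which never passed: -0.026 with equal depth, and -0.13 to 0.22 with 1 library left out. Directions of camera or fry turned 28 times, only for lists with adjusted p above 0.3, and the cause was not tested. The medians of those lists were as follows. The direction that turned is that of the test, and the median need not change sign. Fry gives no median, so the median of the main fit stands beside its turns. LXR targets had 0.00 with RLE scaling, -0.0029 with equal depth, 0.0055 in the main fit (turned by fry) and -0.027 to 0.043 with 1 library left out. Chemokines had 0.63 without scaling, 0.36 at a mean of 1 CPM, 0.58 in the main fit (turned by fry) and 0.21 to 0.64 with 1 library left out. Ribosomal proteins had 0.035 without scaling, -0.0062 without the filter, -0.023 with the replicate block, 0.015 without pair 3 and -0.047 to 0.025 with 1 library left out. Angiogenic factors had -0.22 with limma-voom and -0.28 to -0.050 with 1 library left out. P53 targets had 0.061 with the replicate block and 0.021 to 0.066 with 1 library left out. With 1 library left out, macrophage identity had 0.036 to 0.10 and fatty acid synthesis -0.064 to 0.081. Arg1, Epor and Nos2 lie near or below 2 CPM, and whether more depth would change their results was not tested.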

Other observations

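The test of the dendritic markers alone, the marker medians with libraries left out, the thinning to equal depth and the demand that the interval of a target list exclude 0 were tests chosen after the data were seen. The wells also carried transcripts that mark other bone marrow cells, and whether such cells or the macrophages made them was not tested. All 8 tested mast cell and basophil markers changed, 6 falling and 2 rising (6 and 2 adjusted over the list alone; camera adjusted p = 0.195, 0.0398 without conditioned-medium replicate 2 and 0.697 with an estimated correlation). Prss34, a basophil protease gene, went from 9.40 ± 3.00 to 3.13 ± 1.17 CPM and Mcpt8 from 2.52 ± 0.395 to 0.873 ± 0.333 CPM, while Hdc and Il4 rose. Of 14 neutrophil markers, 4 rose and 2 fell (8 and 2 adjusted over the list alone, and 10 and 3 with the replicate block), with the collagenase gene Mmp8 2.07-fold higher and the granule gene Camp 1.86-fold lower. Their camera adjusted p was 0.0697, and 0.0354 with the replicate block, 0.00345 without conditioned-medium replicate 3 and 0.0264 without untreated replicate 3. With the block and an estimated correlation it was 0.889. Of 10 lymphocyte markers, 0 rose and 1 fell (0 and 1 adjusted over the list alone, and 1 and 3 with the replicate block; camera adjusted p = 0.483), and the only tested erythroid marker, Epor, had a log2 fold change of 0.04 (SE 0.24). Of 14 stromal markers, 0 rose and 1 fell (0 and 0 adjusted over the list alone, and 9 and 1 with the replicate block; camera adjusted p = 0.437, 0.0354 without untreated replicate 1 and 0.931 with an estimated correlation). Col1a1, picked after its values were seen, was highest in well 1 of both groups, at 23.8, 4.50 and 11.4 CPM in untreated wells 1 to 3 and 26.2, 11.3 and 9.19 CPM in the conditioned-medium wells.

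Further lists moved in both directions. Of 25 phagocytosis receptor genes, 10 rose and 8 fell (11 and 9 adjusted over the list alone), with the beta-glucan receptor gene Clec7a 2.65-fold lower and Axl 2.36-fold lower. Their camera adjusted p was 0.0647, and 0.0417 without conditioned-medium replicate 1 and 0.00212 without conditioned-medium replicate 3. With all libraries it was 0.0383 without scaling, 0.0464 with robust dispersion, 0.00461 without the filter and 0.0281 for protein-coding genes only, but 0.224 with the replicate block, 0.379 with limma-voom and 0.697 with an estimated correlation. Of 21 angiogenic and growth factor genes, 4 rose and 8 fell (4 and 8 adjusted over the list alone; camera adjusted p = 0.853), with Thbs1 and Vegfa among the rises and Pdgfb 2.25-fold lower. Camera pointed up there while the median was -0.20. Of 28 matrix remodelling genes, 5 rose and 7 fell (6 and 9 adjusted over the list alone, and 11 and 9 with the replicate block; camera adjusted p = 0.530), with Plau 2.25-fold lower. Stress lists had more falls than rises: 7 against 3 of 30 integrated stress response genes (12 and 5 adjusted over the list alone, and 11 and 5 with the replicate block; camera adjusted p = 0.112), 7 against 3 of 22 unfolded protein response genes (7 and 3 adjusted over the list alone; 0.311), 10 against 4 of 25 oxidative stress genes (10 and 4 adjusted over the list alone, and 10 and 7 with the replicate block; 0.437) and 5 against 1 of 15 heat shock genes (5 and 1 adjusted over the list alone; 0.437). Atf3 was 2.06-fold lower. Of 14 iron handling genes, 3 rose and 6 fell (5 and 6 adjusted over the list alone; 0.534), and of 18 p53 targets, 3 rose and 4 fell (3 and 4 adjusted over the list alone, and 5 and 5 with the replicate block; 0.962). Of 30 ribosomal protein genes, 1 rose and 1 fell (0 and 1 adjusted over the list alone; 0.989), and of 13 mitochondrially encoded genes, 1 rose and 0 fell (1 and 0 adjusted over the list alone, and 2 and 0 with the replicate block; 0.388).

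The 6 libraries split into 3 and 3 in 10 ways, the real one included, too few for a share under 0.05. The real split alone gave counts as large as its own (1 of 10 for each count). It called 3861 genes (1749 higher, 2112 lower), 653 beyond 2-fold and 483 by glmTreat, against at most 0 in any other split by edgeR. It called 14 lists, against 9 to 13 in the other splits and at most 10 in the 3 others that also part all 3 pairs. The remaining splits keep some pairs together. Every other split mixes libraries of both groups and so keeps part of the treatment difference, so it is no reference without effect.

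Leaving out any 1 library gave medians of the interferon response list no higher than -1.05, which argues against one outlying well. Thinning to equal depth left the median at -1.24. Levels were already scaled to the library totals, so thinning could hardly move it and does not decide whether depth played a part. The median of the dendritic and lymphocyte markers together (21 tested) lay 0.705 above that of the interferon list (95% bootstrap interval 0.070 to 1.35), but only 1 of 10 lymphocyte markers changed. The bootstrap intervals here and below resampled genes as if independent, not wells, so they leave out the spread between wells. The 11 dendritic markers alone, tested after that result was seen, had a median of -0.98, which lay 0.257 above that of the interferon list (interval -0.045 to 1.16), so a loss of dendritic cells stays open. With 1 library left out that difference ran from 0.044 (interval -0.278 to 0.875) without untreated replicate 3 to 0.829 (0.346 to 1.55) without conditioned-medium replicate 3, and the difference for the markers together from 0.517 (-0.075 to 1.08) to 1.16 (0.418 to 1.65). How much of the interferon-induced RNA came from dendritic cells was not measured. A fall of their markers as deep would therefore not show that their loss was the cause. A response of the macrophages to the conditioned medium may also explain the fall of the interferon list. It stays a hypothesis, since the medium's content was not measured here.

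RNA of LL-2 cells carried over with the medium could add transcripts to the treated wells. The 7 tested carcinoma markers had a median log2 fold change of 0.049 (95% bootstrap interval -0.460 to 0.351), which leaves carry-over open. That median fell below 0 without conditioned-medium replicate 1 (-0.33), without untreated replicate 2 (-0.095), with limma-voom (-0.071) and with equal depth (-0.064), and was 0.17 without conditioned-medium replicate 3 and 0.60 without the filter. Of them 1 rose and 1 fell (1 and 1 adjusted over the list alone, and 1 and 2 with the replicate block; camera adjusted p = 0.483), and the fall was that of Met, from 21.7 ± 3.14 to 7.49 ± 0.448 CPM. Among markers too low to test, Krt18 had 3 counts in the untreated and 2 in the conditioned-medium libraries, Epcam 0 and 2, Krt7 3 and 10, and Krt19 1 and 13.

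The rises of F13a1, Thbs1, Cd163, Vcan, Fkbp5 and Socs3 prompted 3 lists of targets whose values had not been seen. The targets were measured in the same libraries, and some, among them Il1r2, Vegfa and Il10, already stood in the fixed lists. The 3 lists are therefore no independent check. Their camera p-values were adjusted over these 3 lists alone, apart from the fixed lists. Such p-values cannot be set beside the adjusted p-values of the fixed lists, which were corrected for more tests. Of 26 glucocorticoid receptor targets, 16 rose and 4 fell, with a median of 0.456 (95% bootstrap interval 0.083 to 0.764; camera adjusted p = 0.000154, and adjusted p = 0.0318 with an estimated correlation), though Sgk1 and Anxa1 fell. Of 15 STAT3 targets, 7 rose and 2 fell, with a median of 0.334 (interval 0.008 to 0.670; camera adjusted p = 0.00161, and adjusted p = 0.0707 with an estimated correlation). Of 15 cAMP and CREB targets, 5 rose and 5 fell, with a median of 0.1 (interval -0.571 to 0.794), so that list decides nothing although its camera adjusted p was 0.00729, and 0.0749 with an estimated correlation. A glucocorticoid type and a STAT3 type response may each contribute, but the lists share targets and are not specific, and no hormone or cytokine was measured here. The intervals resampled genes and not wells, and that of the STAT3 list barely excluded 0.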
